A study of Mus musculus with 5 samples.

How the data were processed

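Single-cell RNA sequencing had been carried out on dissociated developing mouse cerebellum with 10x Chromium 3′ kits, versions v3 and v3.1, per the labels' protocols. Cell Ranger and the mouse genome build mm10 are named per the submitters' processing notes. The filters applied to cells and genes, and the way doublets were treated, are not given in the sources used here. The deposited table held natural log values for 15971 genes in 6987 cells. A second deposited file gave the library of each cell and no cell type.

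The unit was worked out from the values. The natural log values deposited by the authors, back-transformed, summed to 10000 in every cell, so that each value was ln(1 + 10000 × UMI count / total UMI count of the cell). All 29540669 values above 0 (100%) were whole multiples of the lowest value in their cell, with a tolerance of 0.01 of a count and a largest deviation of 0.000894. UMI counts (unique molecular identifiers, which count molecules) were recovered in this way and used for depth, intervals and thinning. Each cell had 2106 to 6549 genes detected and each gene was detected in at least 10 cells. No mitochondrially encoded gene and no Hox gene was among the genes analysed here.

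Libraries were grouped by title. 4 of the 5 batch names matched a title, and the remaining batch was taken as the EomesCreER e16 library because it was the batch left. RL e13 replicate 2 carries e13 in its title and e14 in its age tag. The title set the main grouping and the age tag an alternative. Nothing states that replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

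Cell types had to be rebuilt, because the planned design assumed deposited names. Counts scaled per cell were reduced to 2000 variable genes after 122 genes of the fixed lists to be reported were left out. The other cell type markers and the neuronal differentiation genes stayed in, so the clusters are not independent of them. A graph of 20 neighbours on 30 principal components was clustered with leidenalg 0.10.2 and igraph 0.11.9 at resolution 1 (17 clusters), with resolution 2 (27 clusters) as an alternative. Clusters were named from marker lists fixed before the data were examined. The scoring rule that turned markers into names was chosen after the clusters had been seen. A progenitor-like cluster needed a higher score for the rhombic lip or the radial glia list than for the granule lineage lists, so the class pools both kinds of progenitor. 5 clusters were called progenitor-like and 5 GCP-like (granule cell progenitor-like). The results of a further class, and of some genes, are not reported here. Among the progenitor-like clusters, clusters 15 and 16 were led by roof plate genes. Clusters 5 and 6 were postmitotic and stayed unnamed. No doublet caller was run. Leaving out the 5% of cells with the most UMIs in each library served as an alternative.

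For each class and library with 20 or more cells, back-transformed values were averaged over cells and scaled to a sum of 1000000, called CPM here. Tests were run on log2(CPM + 5), a scale that understates changes of genes at low levels. Genes with a mean of 10 CPM or more over the profiles compared were kept. Classes were compared with limma 3.58.1 (trend, moderated test, R 4.3.3) with the library as a block, and adjusted p-values are Benjamini-Hochberg values over all genes tested, with 0.05 as the threshold. GCP-like cells were compared with progenitor-like cells over 4 libraries. The comparison of cluster 5 with GCP-like cells over 4 libraries was added after the clusters had been seen. The e14 and e13 libraries were compared on the mean of both classes with 20 or more cells in all 4. The e16 library, the only one of its group, was set beside the 4 RL libraries with no test. The annotation makes no split of the rhombic lip into ventricular and subventricular zones, and no cluster was named for the glutamatergic nuclei, so these planned comparisons were not made.

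The 31 gene lists were fixed before the data were examined. Lists with 3 or more members tested were examined with camera (preset correlation 0.01), camera with an estimated correlation, and fry, each adjusted over lists. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Named genes were fixed by rule: a set of lineage and medulloblastoma genes throughout, the 5 highest and 5 lowest called genes of each comparison with the same direction in every library and 50 CPM or more in the higher class, and up to 3 called members of each list. For the e16 library the rule took the 10 highest and 10 lowest differences outside the range of the RL libraries. Genes at another level in 1 library were picked by fold (4 or more) and named after their values were seen.

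Each test was checked on simulated profiles with 200 changed genes and a dispersion of 0.03. At a simulated log2 change of 1, 97.9% of changed genes were recovered for GCP-like against progenitor-like cells (8348 genes), 91.7% for cluster 5 against GCP-like cells (8143 genes) and 95.2% for e14 against e13 (8096 genes). At a change of 2 the shares were 100% in each. Of all calls, 5.71%, 3.54% and 3.96% were false, in the same order. All simulated libraries shared a common baseline, with no library effect. The shares recovered therefore do not give the power in the real libraries. A lack of calls between e14 and e13 by title does not show that changes are absent.

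Shares of cells are given with 95% Wilson intervals and summed counts with exact Poisson intervals. These cover counting error only and leave out differences between animals. Where shares of cells with a UMI were compared, cells were thinned to 4000 UMIs, which left out 4 cells. Alternatives were pseudocounts of 1 and 20, no expression filter, TMM scaling, no library block, 50 cells per profile, voom on the recovered counts, the age-tag grouping, the replicate number as a block, all cells pooled, and each library left out in turn. Added after the data had been seen were the removal of cells with the most UMIs, resolution 2, the removal of roof plate-like clusters from the tests, and every alternative of the cluster 5 comparison. Gene positions are from GENCODE mouse release M21 on mm10. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.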

Results

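Gene expression was measured in single cells of the developing mouse cerebellum, in a series on the origin of Group 3 and Group 4 medulloblastoma. The rhombic lip (RL) is the dorsal germinal zone that produces the glutamatergic neurons of the cerebellum. The 5 libraries form 3 groups by title, with 1 EomesCreER e16 library, 2 RL e14 libraries and 2 RL e13 libraries. RL e13 replicate 2 carries an age tag of e14 against its title. EomesCreER names a mouse line in which Cre is driven from Eomes, and how its cells were selected is not given in the sources used here. The table held 15971 genes. The e16 library held 2676 cells and 30064674 UMIs, with a median of 10346 UMIs per cell. RL e14 replicate 1 held 1046 cells and 17331119 UMIs (median 15855), and RL e14 replicate 2 held 741 cells and 15095334 UMIs (median 19970). RL e13 replicate 1 held 706 cells and 13607965 UMIs (median 18692), and RL e13 replicate 2 held 1818 cells and 33502151 UMIs (median 17837). Levels are means over cells in CPM (UMIs scaled to a sum of 1000000 per cell), and intervals on shares and counts cover counting error only. Genes of GABAergic interneurons reached at most 5.51 CPM in any profile of a class and library, genes of microglia 5.50, photoreceptor genes 5.41 and meningeal genes 9.30. The highest values were 24.0 for oligodendrocyte genes, 40.5 for endothelial genes and 43.2 for red blood cell genes, against 1410 for roof plate and choroid plexus genes.

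The first comparison asked which cells of the rhombic lip lineage each library held. Progenitor-like cells, which carry rhombic lip and radial glia genes such as Sox2, made up 91.9% of RL e13 replicate 1 (95% Wilson interval 89.7 to 93.7, 649 cells). They made up 35.3% of RL e13 replicate 2 (33.1 to 37.5, 642 cells), 19.8% of RL e14 replicate 1 (17.5 to 22.3, 207 cells) and 19.3% of RL e14 replicate 2 (16.6 to 22.3, 143 cells). Granule cell progenitor-like cells (GCP-like), which carry Atoh1 and Barhl1, were the most frequent class in RL e14 replicate 1 (68.4%, 65.5 to 71.1), RL e14 replicate 2 (60.1%, 56.5 to 63.5) and RL e13 replicate 2 (53.8%, 51.5 to 56.1). They made up 7.37% (5.66 to 9.53) of RL e13 replicate 1 and 4.60% (3.87 to 5.46) of the e16 library. Cluster 5, postmitotic cells led by Cbln2 and Cadps2, made up 16.9%, 10.5% and 10.7% of RL e14 replicate 2, RL e14 replicate 1 and RL e13 replicate 2, and 0.708% of RL e13 replicate 1. Cluster 6, postmitotic cells led by Syt4 and Tlx3, took 98.9% of its 475 cells from the e16 library, where it made up 17.6% (16.2 to 19.1).

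By title, the share of GCP-like cells was 64.2% ± 5.87 at e14 and 30.6% ± 32.8 at e13 (SD, n = 2 against 2, exact two-sided permutation p = 0.333, the smallest this design allows). Progenitor-like cells made up 19.5% ± 0.347 at e14 and 63.6% ± 40.0 at e13 (exact p = 0.333), and cluster 5 13.7% ± 4.49 and 5.72% ± 7.08 (exact p = 0.667). With RL e13 replicate 2 grouped by its age tag, GCP-like cells made up 60.7% ± 7.30 of 3 libraries and 7.37% of the remaining 1, and progenitor-like cells 24.8% ± 9.11 and 91.9% (exact p = 0.25 for both, the smallest that 3 against 1 allows). These designs cannot show a difference between ages at 0.05, and how the tissue was dissected is not given in the sources used here.

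**Figure D1:**
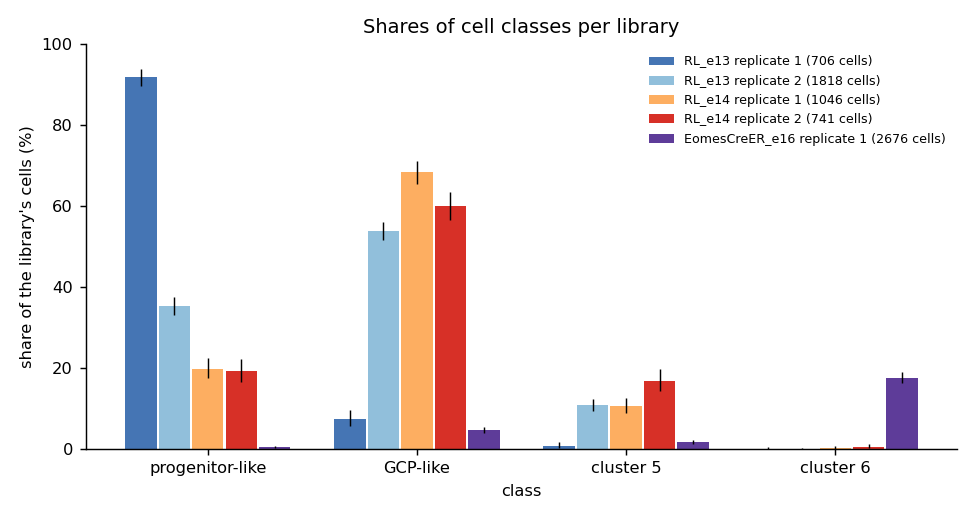
Share of cells in percent (y axis) of 4 classes in each of the 5 libraries, with 95% Wilson intervals. Progenitor-like cells reach 91.9% in RL e13 replicate 1, and GCP-like cells reach 53.8% to 68.4% in the other 3 RL libraries.

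GCP-like cells were compared with progenitor-like cells to describe the step from the rhombic lip to the granule lineage. In all 4 RL libraries GCP-like cells had more Barhl1, a homeobox gene of the granule lineage (420 ± 55.7 against 5.92 ± 2.47 CPM, SD, n = 4), and more Atoh1, the proneural factor of rhombic lip derivatives (439 ± 112 against 55.9 ± 31.1). The log2 differences were 5.30 ± 0.11 (SE, limma with Benjamini-Hochberg adjustment, adjusted p = 3.4e-07) for Barhl1 and 2.95 ± 0.11 (adjusted p = 2.3e-06) for Atoh1. Eomes, a T-box factor of glutamatergic lineages, stood at 37.9 ± 6.50 CPM in GCP-like and 0.304 ± 0.260 in progenitor-like cells (log2 difference 3.00 ± 0.13, limma adjusted p = 4.3e-06). Sox2, a stem cell factor, fell from 494 ± 68.1 to 66.0 ± 9.75 CPM (log2 difference -2.81 ± 0.09, limma adjusted p = 7.7e-07), and Wls, needed for Wnt secretion and a marker of the rhombic lip, from 235 ± 31.2 to 69.8 ± 29.8 (-1.76 ± 0.17, adjusted p = 0.00017). Otx2, a homeobox gene amplified in medulloblastoma, did not pass the test, with 121 ± 55.9 against 88.8 ± 57.5 CPM (log2 difference 0.52 ± 0.19, limma adjusted p = 0.073, higher in 4 of 4 libraries). It passed with TMM scaling (0.61, adjusted p = 0.049) and with the roof plate-like clusters left out of the progenitors (2.03, adjusted p = 0.0030), over a range of 0.0030 to 0.48 among its alternatives. The GCP-like class was mixed for these genes. Its cluster 13, with the highest Atoh1 (642 CPM), had Eomes at 0 and Otx2 at 21.5. The other GCP-like clusters had Eomes at 43.0 to 85.9, Otx2 at 106 to 246 and Atoh1 at 295 to 442 CPM. Those clusters include cells of the e16 library, while cluster 13 holds 0 of them.

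The highest differences among genes with 50 CPM or more were those of Nrn1, which encodes a neurite growth factor (5.45 ± 0.10, 399 against 4.27 CPM), Insm1, a zinc finger gene of delaminating progenitors (5.45 ± 0.12, 585 against 8.72), Barhl1, Igfbpl1 (4.94 ± 0.10) and Uncx (4.79 ± 0.19). Their limma adjusted p-values were at most 2.3e-06. The lowest were those of Ttyh1 (-5.03 ± 0.13, 5.07 against 332 CPM), Gdf10 (-4.88 ± 0.19), the Notch target Hes5 (-4.85 ± 0.12, 14.2 against 553), the endothelin receptor gene Ednrb (-4.83 ± 0.34) and the radial glia gene Fabp7 (-4.45 ± 0.13, 204 against 4642). Pax6 rose by 1.29 ± 0.15 (limma adjusted p = 0.00047) and Olig3, a rhombic lip gene, by 1.02 ± 0.24 (adjusted p = 0.014). The Olig3 call was lost without the library block (limma adjusted p = 0.36, the highest of its alternatives) and without RL e14 replicate 1 (adjusted p = 0.068). On the mm10 genome Barhl1 lies on chromosome 2 from 28907679 to 28916668, Atoh1 on chromosome 6 from 64729125 to 64731245 and Eomes on chromosome 9 from 118478212 to 118486132. Sox2 lies on chromosome 3 from 34650405 to 34652461, Wls on chromosome 3 from 159839672 to 159938664 and Otx2 on chromosome 14 from 48657677 to 48673819.

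**Figure D2:**
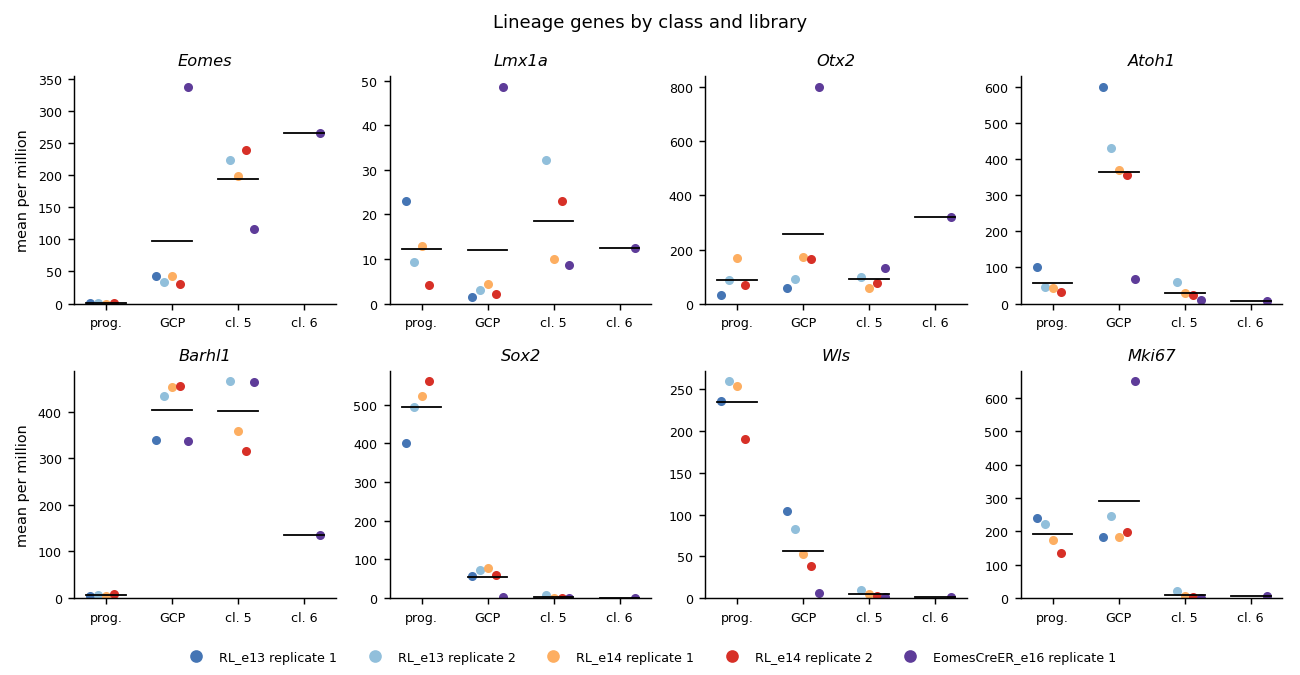
Mean CPM (y axis) of 8 lineage genes in 4 classes, with 1 point per library and a black line at the mean over libraries. Eomes lies at 0.304 in progenitor-like, and 30.9 to 43.5 in RL GCP-like cells, while Mki67 lies at 202 in RL GCP-like and 193 in progenitor-like cells.

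Genes of neuronal differentiation rose together in GCP-like cells, with 11 of 11 tested members higher, 11 also adjusted over the list alone. Among them were Gap43, a growth cone gene (4.07 ± 0.12), and Dcx, which encodes a microtubule protein of migrating neurons (3.22 ± 0.15). Camera gave an adjusted p of 7.8e-12, and adjusted p = 0.12 with an estimated correlation. Of 9 genes of differentiating granule cells 7 were higher, Neurod2 by 4.04 ± 0.14, and Zic4 was lower, with the same counts adjusted over the list alone (camera adjusted p = 1.3e-05, and adjusted p = 0.25 with an estimated correlation). All 8 glia and radial glia genes were lower, adjusted over the list alone also 8 (camera adjusted p = 4.0e-06, and adjusted p = 0.32 with an estimated correlation). Of 10 rhombic lip genes 9 were lower and Olig3 was higher, with the same counts adjusted over the list alone (camera adjusted p = 4.3e-06, and adjusted p = 0.15 with an estimated correlation). Among 9 granule cell progenitor genes 5 were higher and Boc and Zic1 lower, the same adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.26 with an estimated correlation). Without the expression filter the camera adjusted p of this list was 0.22. The Boc call was lost in 5 alternatives and that of the hedgehog receptor gene Ptch1 in 3. The cell type lists check the class names. Neither they nor the neuronal differentiation genes, which stayed in the clustering, are independent evidence.

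Of 15 G2 and M phase genes 0 passed with limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.42). Mki67, a proliferation marker, stood at 202 ± 29.6 against 193 ± 47.4 CPM (limma log2 difference 0.09 ± 0.13). S phase genes passed in 5 of 15 cases, all higher, 7 adjusted over the list alone (camera adjusted p = 0.00099, and adjusted p = 0.54 with an estimated correlation), among them Tyms (0.60 ± 0.10) and Mcm6 (0.52 ± 0.11). Of 10 Notch pathway genes 6 were lower, including the receptor gene Notch1 (-2.64 ± 0.10, 24.2 against 179 CPM). Dll1, Dll3 and Hey1 were higher, with the same counts adjusted over the list alone (camera adjusted p = 0.024, and adjusted p = 0.48 with an estimated correlation). Of 6 BMP response genes 5 were lower, Id1 by a log2 difference of -3.84 ± 0.12, and Smad7, an inhibitor of the pathway, was higher by 1.29 ± 0.09, again the same adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.25 with an estimated correlation). Wnt response genes went both ways, with Nkd1 and Sp5 (2.72 ± 0.15) higher and Axin2, Znrf3, Wnt1 and Rspo1 lower among 7. Adjusted over the list alone, 3 were higher and 4 lower (camera adjusted p = 0.70). Among 9 dissociation and immediate early genes 7 were lower, 7 also adjusted over the list alone (camera adjusted p = 0.0048, and adjusted p = 0.48 with an estimated correlation). Fos fell from 863 ± 311 to 170 ± 36.0 CPM. These stress genes moved in the same direction as the glia and rhombic lip genes.

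Medulloblastoma genes and corepressor genes both had members that differed. Of 17 tested Group 3 and Group 4 medulloblastoma genes, Mycl, Cbfa2t2, Cbfa2t3, Runx1t1 and Chd7 were higher in GCP-like cells and Sncaip and Cdk6 lower. Adjusted over the list alone, 9 were higher and 3 lower (camera adjusted p = 0.024, and adjusted p = 0.25 with an estimated correlation). With TMM scaling the camera adjusted p was 0.057, the only alternative that ended this call. Cbfa2t3, a transcriptional corepressor gene, stood at 188 ± 8.20 against 4.88 ± 2.49 CPM (log2 difference 4.32 ± 0.13, limma adjusted p = 7.7e-07), and Cbfa2t2, its paralog, at 97.7 ± 10.3 against 20.8 ± 5.60 (2.02 ± 0.09, adjusted p = 5.5e-06). Cdk6, a G1 kinase gene, fell from 79.3 ± 26.1 to 8.33 ± 4.97 CPM (log2 difference -2.68 ± 0.09, limma adjusted p = 1.0e-06). Of 14 genes of the CBFA2T corepressor complex 6 were higher, including Rcor2 (2.21 ± 0.09, 151 against 29.2 CPM), and Tcf12 was lower, the same adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.25 with an estimated correlation). Kdm6a, a histone demethylase gene mutated in medulloblastoma, stood at 28.7 ± 4.31 against 36.2 ± 2.77 CPM (-0.30 ± 0.11, limma adjusted p = 0.078). Cbfa2t2 lies on chromosome 2 from 154436481 to 154539356 and Cbfa2t3 on chromosome 8 from 122625141 to 122699109.

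Over all 8419 genes tested with limma, 1123 were higher and 1799 lower in GCP-like cells (2190 against 1641 cells, n = 4 pairs), and 612 and 1218 of the 6701 genes that had not been used to cluster. With TMM scaling 1580 were higher and 1329 lower, so that the share of calls that were higher moved from 38.4% to 54.3%. Without the library block the counts were 714 and 1212, and without RL e13 replicate 2 they were 703 and 1140. The classes were clustered from the same values, so the counts describe how far apart the clusters lie.

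Cluster 5 was compared with GCP-like cells in 3 RL libraries and the e16 library, a comparison added after the clusters had been seen. Its cells were low in cycling genes, with Mki67 at 7.68 ± 8.63 against 319 ± 222 CPM (SD, n = 4, log2 difference -4.70 ± 0.52, limma with Benjamini-Hochberg adjustment, adjusted p = 0.00067). Atoh1 fell from 306 ± 162 to 30.3 ± 20.7 CPM (-3.06 ± 0.21, adjusted p = 0.00020). A part of the wide spread in GCP-like cells comes from the e16 library, with Mki67 at 649 and Atoh1 at 68.8 CPM. Mapt (4.36 ± 0.15, 745 against 32.5 CPM), the synaptic organiser gene Cbln2 (3.98 ± 0.24, 135 against 3.97), Ina (3.78 ± 0.24) and Nefl (3.55 ± 0.17) were the highest. Reln, secreted by granule and nuclear neurons, rose by 1.67 ± 0.10 to 425 ± 51.9 CPM, and the receptor tyrosine kinase gene Erbb4 by 1.89 ± 0.07 to 272 ± 14.5 CPM (limma adjusted p = 9.6e-05). Eomes was higher in the 3 RL libraries, by 2.07 to 2.76, and lower in the e16 library (-1.51), where GCP-like cells carry Eomes and their name is uncertain, giving 1.47 ± 0.68 (limma adjusted p = 0.12). Without the e16 library the difference was 2.46 (adjusted p = 5.5e-07, and up to 0.35 over its alternatives). Slc17a6, Otx2 and Pax6 passed here but lost their calls in 8, 4 and 4 alternatives.

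Neuronal differentiation genes were higher in 11 of 12 cases, 12 adjusted over the list alone (camera adjusted p = 3.4e-07, and adjusted p = 0.53 with an estimated correlation), with Dcx at 678 against 123 CPM. These genes stayed in the clustering, so this is not independent evidence. All 15 S phase and all 15 G2 and M phase genes were lower, 15 of each adjusted over the list alone (camera adjusted p = 3.3e-09 and 4.3e-09, and adjusted p = 0.53 with an estimated correlation for both). Of 10 genes of differentiating granule cells 7 were higher, 7 adjusted over the list alone (camera adjusted p = 0.0097, and adjusted p = 0.58 with an estimated correlation). Of 5 Wnt response genes Nkd1 (-2.37 ± 0.16), Sp5, Lef1 and Znrf3 were lower, 5 adjusted over the list alone (camera adjusted p = 0.020, and adjusted p = 0.53 with an estimated correlation). Of 17 Group 3 and Group 4 medulloblastoma genes Smarca4, Cdk6, Runx1t1 and Erbb4 were higher and Myc, Mycl, Mycn, Otx2, Cbfa2t2 and Cbfa2t3 lower. The counts were the same adjusted over the list alone, and the list as a whole did not stand apart (camera adjusted p = 0.997). Runx1t1 rose from 55.7 to 271 CPM (2.19 ± 0.30), and Cbfa2t3 fell from 167 to 104 CPM (-0.67 ± 0.10, limma adjusted p = 0.0019). Of 8303 genes tested with limma, 2226 were higher and 2047 lower (474 against 2261 cells), 1542 and 1485 of the 6595 that had not been used to cluster. Without RL e14 replicate 1 the counts were 1512 and 1334, and without RL e14 replicate 2 they were 1479 and 1390. Without the e16 library they were 2620 and 2495. Erbb4 lies on chromosome 1 from 68032186 to 69108059 and Runx1t1 on chromosome 4 from 13743436 to 13893649.

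The e14 and e13 RL libraries were compared on the mean of progenitor-like and GCP-like cells, to ask how expression in these classes differed between the libraries of each age. The clusters behind the classes differed too. Of the 649 progenitor-like cells of RL e13 replicate 1, 426 lay in cluster 7 and 1 in cluster 1, against 12 and 400 of 642 in RL e13 replicate 2, 1 and 103 of 207 in RL e14 replicate 1 and 0 and 109 of 143 in RL e14 replicate 2. Of its 52 GCP-like cells 24 lay in the S phase cluster 11, against 161 of 978, 87 of 715 and 58 of 445 in the same order. Roof plate-like cluster 15, where Otx2 stood at 427 CPM, held 5 of the 649 progenitor-like cells of RL e13 replicate 1, 94 of 642, 72 of 207 and 19 of 143, next to Otx2 at 31.2, 88.2, 167 and 68.4 CPM in these cells. With the cluster levels of the other RL libraries, which have few cells of cluster 7, the make-up of RL e13 replicate 1 alone gives Tnc at 57.8 and Sparcl1 at 540 CPM in progenitor-like cells, where 11.8 and 222 were measured. In GCP-like cells, which hold no cluster 15, Otx2 stood at 171 and 165 CPM in the e14 and 57.1 and 91.8 in the e13 libraries, where make-up alone gives 115, 128, 158 and 157. Each make-up value leaves its own library out of the reference, so the reference differs between libraries. The order of the make-up values therefore shows no effect of make-up on Otx2. With the roof plate-like clusters left out, the log2 difference of Otx2 by title on the mean of both classes was 0.26. By title no gene passed the test. Otx2 had a log2 difference of 1.06 ± 0.34, Olig3 of -1.69 ± 0.52 and Wls of -0.57 ± 0.15 (SE, n = 2 against 2, limma with Benjamini-Hochberg adjustment, adjusted p = 0.25 for each). Without RL e13 replicate 2, Otx2 (1.56), Olig3 (-2.53) and Atoh1 (-1.02) passed, but RL e13 replicate 1 is then alone on its side and the spread comes from the e14 libraries only. With it, Atoh1 had -0.64 ± 0.24, Cbfa2t2 -0.37 ± 0.12, Cbfa2t3 0.03 and Eomes -0.06. By the age tag RL e13 replicate 1 is again alone, the spread comes from the other 3 libraries only, and the test shows how this 1 library differs from them. In those 3, Etv5, a target of FGF signalling, was higher by 2.44 ± 0.22 (limma adjusted p = 0.0083), Egr1, an immediate early gene, by 2.08 ± 0.14 (adjusted p = 0.0035) and Tnc, a matrix gene of radial glia, by 1.85 ± 0.21 (adjusted p = 0.014). Tnc stood at 118 CPM in cluster 1 and 12.6 in cluster 7. Atoh1 was lower by that grouping (-0.94 ± 0.16), as was Neurod2 (-1.42 ± 0.19). In progenitor-like cells, make-up alone gives Atoh1 at 144 CPM in RL e13 replicate 1, above the 102 measured. It gives 40.8 to 45.7 in the others, each with its own library left out of the reference. In GCP-like cells of RL e13 replicate 1 it gives 424, below the 600 measured. Xist, which silences the inactive X chromosome, was also higher (2.99 ± 0.41), at 926, 392 and 641 CPM in GCP-like cells against 28.5 in RL e13 replicate 1. The value of 28.5 rests on 52 cells. In progenitor-like cells Xist stood at 995, 361 and 667 CPM against 179 in RL e13 replicate 1. No sex is listed for these libraries, so a difference in their sex make-up cannot be told apart. Rpl26 was higher by 4.35 ± 0.71, but 38.9% of the words at its 3′ end occur in other genes, so its level is uncertain.

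By title 0 of the 8 glia and radial glia genes passed with limma and 0 adjusted over the list alone (Gdf10, Slc1a3 and Tnc, 3 genes, at an unadjusted p under 0.05), with a median log2 difference of 0.43 (camera adjusted p = 0.0023, and adjusted p = 0.86 with an estimated correlation). Without RL e13 replicate 1 the camera adjusted p was 0.18, and with all cells pooled 0.263 with the direction turned. Of 9 immediate early genes 0 passed with limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0042, and adjusted p = 0.86 with an estimated correlation). Without RL e13 replicate 1 it was 0.25, and with all cells pooled 0.33. By the age tag Tnc and Sparcl1, the latter at 849 CPM in cluster 1 and 236 in cluster 7, were higher in the 3 libraries among the glia genes, 6 adjusted over the list alone (camera adjusted p = 1.1e-07, and adjusted p = 0.65 with an estimated correlation). Fos, Junb, Egr1 and Ier2 were higher among the immediate early genes, 6 adjusted over the list alone (camera adjusted p = 8.4e-09, and adjusted p = 0.65 with an estimated correlation). S phase genes were lower than in RL e13 replicate 1, with its larger share of GCP-like cells from the S phase cluster, with 1 of 15 passing and 11 adjusted over the list alone (camera adjusted p = 1.2e-09, and adjusted p = 0.65 with an estimated correlation). Of 15 G2 and M phase genes none passed with limma over all genes and 2 were higher adjusted over the list alone (median log2 difference 0.35, camera adjusted p = 0.00093, and adjusted p = 0.93 with an estimated correlation, fry adjusted p = 0.53). Mki67 had -0.14.

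By title limma called 0 genes higher and 0 lower of 8419, with 1316 at an unadjusted p under 0.05. The groups did not overlap for 4306 genes or 51.1%, where chance gives 33.3%. Grouped by the age tag, 66.7% of genes did not overlap, where chance gives 50%. Genes are correlated over so few libraries, so such shares can lie far from chance with no effect of age. By the age tag 48 genes were higher and 20 lower than in RL e13 replicate 1. By title, without RL e13 replicate 2 the counts were 214 and 304, without RL e13 replicate 1 they were 5 and 7, and without RL e14 replicate 1 they were 1 and 0, each with 1 library alone on its side. Whether the difference between GCP-like and progenitor-like cells changed with age was tested as an interaction with limma, which called 0 genes (441 at an unadjusted p under 0.05, smallest adjusted p = 0.755). RL e13 replicate 2 lay nearer to the e14 libraries than to RL e13 replicate 1, with an SD of the log2 difference over 8419 genes of 0.234 and 0.262 against 0.299 on the mean of both classes. In progenitor-like cells alone it lay nearer to RL e14 replicate 1 (0.273) but further from RL e14 replicate 2 (0.334) than from RL e13 replicate 1 (0.317). RL e13 replicate 1 had 52 GCP-like cells, against 445 to 978 in the other RL libraries. Sampling noise from so few cells widens its distances, so they are not on an equal footing.

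**Figure D3:**
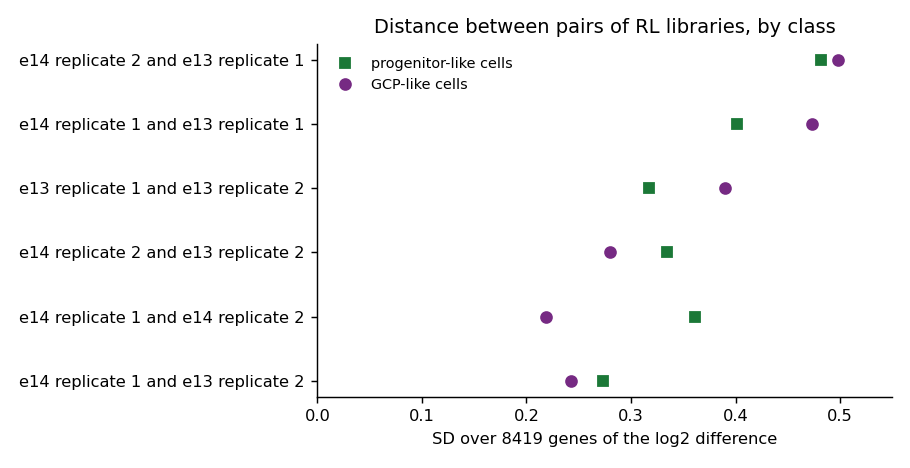
SD of the log2 difference over 8419 genes (axis in log2 units) for the 6 pairs of RL libraries, with squares for progenitor-like and circles for GCP-like cells. In GCP-like cells the 3 pairs with RL e13 replicate 1 lie at 0.390 to 0.498 and the other 3 at 0.219 to 0.280. This library has 52 GCP-like cells, against 445 to 978 in the others, so sampling noise is higher in its pairs.

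The e16 library was set beside the 4 RL libraries in GCP-like cells, the only class with 20 or more cells in all 5. No test was made, because the e16 library has no replicate. Of its 123 GCP-like cells, 62, 40 and 12 came from the G2 and M phase cluster 3, the histone-led cluster 4 and the S phase cluster 11. Their Atoh1, Eomes and Otx2 levels go against a granule cell progenitor name, so the name is uncertain for this library. Its GCP-like cells carried more Eomes, 337 CPM against 30.9 to 43.5 in the RL libraries, and of the neuronal transcription factor genes Barhl2 (211 against 3.06 to 16.9), Neurod4 (191 against 8.42 to 17.4) and Nr2f2 (184 against 9.57 to 14.8). Slc17a6, the glutamate transporter gene VGLUT2, stood at 210 against 14.5 to 22.3 CPM. Atoh1 stood at 68.8 against 356 CPM or more in each RL library, Otx2 at 803 against 57.1 to 171 and Mki67 at 649 against 182 to 245. Sox2 (3.89 against 56.3 to 76.9), the chemokine receptor gene Cxcr4 (18.4 against 140.1 to 203) and the activin antagonist gene Fst (8.68 against 159.6 to 294) were lower. Sparc was listed at 0 against 34.0 to 235. Rpl29 (801 against 0.749 to 13) and Tpm3-rs7 (0.494 against 86.3 to 198) stood furthest apart. However, 67.5% and 51.6% of the words at their 3′ ends occur in other genes, so their levels are uncertain.

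Of 8186 genes, 359 were more than 2-fold higher and 303 more than 2-fold lower than the mean of the RL libraries and outside their range, 845 and 1023 when all cells were pooled. The 15 G2 and M phase genes had a median log2 difference of 1.46, at percentile 100 of 10000 random lists matched on expression, while the 15 S phase genes had -0.27 (percentile 2.44). Neuronal differentiation genes had a median of 0.53 (percentile 99.97), genes of differentiating granule cells of 0.64 (percentile 99.95) and dissociation and immediate early genes of 0.43 (percentile 98.97). Rhombic lip genes had a median of -1.92 (percentile 0), Notch pathway genes of -1.68 (percentile 0), Sonic hedgehog response genes of -1.14 (percentile 0.01) and glia genes of -1.55 (percentile 0.09). The 16 Group 3 and Group 4 medulloblastoma genes had a median of -0.29 (percentile 1.94) and the 14 CBFA2T complex genes of 0.06 (percentile 72.53). Members of the random lists were drawn independently, without the correlation between the genes of a real list. The percentiles therefore describe this library and are no test, also where they lie near 0 or 100. Of the e16 cells of this class, 62 of 123 came from the G2 and M phase cluster, against 94 of 445 in RL e14 replicate 2. Cluster 13, led by Pvalb and Fst and with the highest Atoh1 (642 CPM), held 0 of the 123, against 188 of 978, 87 of 715, 40 of 445 and 6 of 52 in the RL libraries. With the cluster levels of the RL libraries, this make-up alone gives Atoh1 at 348, Fst at 196, Otx2 at 170 and Mki67 at 387 CPM, where 68.8, 8.68, 803 and 649 were measured. Age and mouse line differ together between the e16 and the RL libraries, and so may selection, which is not given in the sources used here.

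The Group 3 and Group 4 medulloblastoma genes were then ranked across classes, in the 3 RL libraries with 20 or more cells of progenitor-like, GCP-like and cluster 5 cells. Of 18 genes ranked, 4 were highest in progenitor-like cells, 7 in GCP-like cells and 7 in cluster 5. Kdm6a, Sncaip and Cdk6 were highest in progenitor-like cells in all 3 libraries, Cdk6 at 88.7 ± 22.3 CPM against 9.95 ± 4.62 and 33.0 ± 14.4 (SD, n = 3). Myc, Mycl, Ctdnep1, Cbfa2t2 and Cbfa2t3 were highest in GCP-like cells in all 3, Cbfa2t3 at 188 ± 10.0 CPM against 5.39 ± 2.79 in progenitor-like and 114 ± 24.7 in cluster 5. Runx1t1, Erbb4, Chd7, Tbr1, Kmt2c, Kmt2d and Smarca4 were highest in cluster 5 in all 3, Runx1t1 at 226 ± 36.3 CPM against 16 ± 1.5 and 60.2 ± 25.0. Otx2 was highest in GCP-like cells in 2 of 3, at 143 ± 44.1 CPM against 108 ± 52.4 and 77.0 ± 21. By the share of cells with a UMI after thinning, 17 of 18 genes were highest in the same class. No test was made of these ranks.

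**Figure D4:**
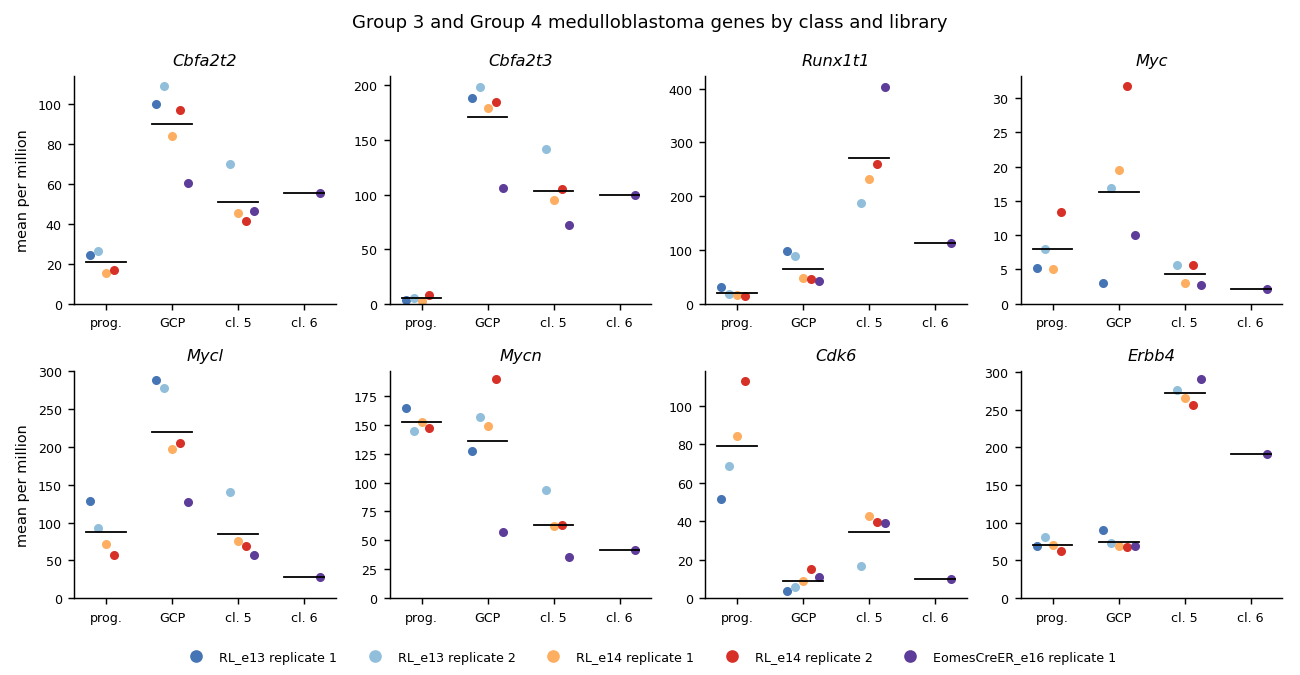
Mean CPM (y axis) of 8 medulloblastoma genes in 4 classes, with 1 point per library and a black line at the mean over libraries. Cbfa2t3 lies at 188 in RL GCP-like cells against 4.88 in progenitor-like cells, and Cdk6 at 8.33 against 79.3.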

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

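The tests of the title against the age tag, of depth, of draws from any cluster, of Gsta4, Lsamp and Nr2f2 and of the other splits of the profiles were chosen after the result was seen. In 134 groups of 4 libraries, 13 held 1 library whose value lay far from the other 3, and chance alone gives about 1 in 20 groups. Of these, 8 lie in the e16 library in the comparison of cluster 5 with GCP-like cells, where that library differs from the others in age and mouse line, so they are not independent of each other.

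Between GCP-like and progenitor-like cells, the log2 difference of Sox2 was -3.13 in RL e14 replicate 2, against -2.73 to -2.68 in the other RL libraries. That of Smo was -0.26 in RL e14 replicate 2, against -0.41 in the others. Nrn1 stood at 5.83 in RL e13 replicate 1, against 5.28 to 5.37.

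Between cluster 5 and GCP-like cells, genes that stood apart in the e16 library fall into lineage genes and cycling genes. Eomes had a log2 difference of -1.51, against 2.07 to 2.76 in the RL libraries, and Slc17a6 of -0.73, against 1.99 to 2.54. Wls stood at -0.70, against -2.62 to -2.43, Dll1 at 0.0019, against -2.81 to -2.37, and Erbb4 at 2.01, against 1.84 to 1.86. The cycling genes Top2a (-7.37, against -4.74 to -4.67), Cenpf (-6.58, against -4.31 to -4.20) and Ccnb1 (-6.02, against -4.25 to -4.09) were further down in the e16 library. In RL e13 replicate 2, En1 stood at 1.01, against 1.56 to 1.66 elsewhere, and Rrm1 at -1.75, against -2.35 to -2.28.

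RL e13 replicate 1 stood apart from the other 3 RL libraries in GCP-like cells and on the mean of both classes. For the clusters that all 4 shared, the tables argue against few cells as the whole cause, while the part of class make-up stays open. With equal numbers of cells from clusters 4, 8 and 11, 55 cells per library, the distance to this library was 1.22 times that among the other 3 (range 1.19 to 1.27 over 20 draws). The same numbers of cells per class from any cluster gave 1.19 (1.15 to 1.26), and all cells 1.47 on the mean of both classes, where less sampling noise enters. These clusters hold 242 of the 706 cells of this library. Cluster 7, with 426, had too few cells elsewhere to be matched, so its part stays open. At resolution 2, the cycling progenitor-like cluster 18 took 206 of its 211 cells from RL e13 replicate 1, and clusters 22 and 25 took 0. Cells of a matched cluster can thus still differ in make-up. The median depth of RL e13 replicate 1 was the highest of the 4 in both classes (25200 UMIs in GCP-like cells, against 16314 to 21934). For GCP-like cells the tables argue against depth as the whole cause. With equal numbers of cells, each thinned to 10000 UMIs, the distance was 1.16 times that among the others in GCP-like cells (1.14 to 1.19 over 20 draws). In progenitor-like cells it was 1.21 times (1.18 to 1.24). The same draws without thinning gave 1.22 and 1.24, so a part of it may go with depth. All cells, at unequal numbers per library, gave 1.84 and 1.24. In progenitor-like cells another library lay about as far off. RL e14 replicate 2 was at 0.334 to 0.482 from the other RL libraries, and RL e13 replicate 1 at 0.317 to 0.482. The values of this class therefore do not set RL e13 replicate 1 apart. Such quotients were computed for RL e13 replicate 1 only. The distance of RL e13 replicate 2 to the e14 libraries was 0.83 of its distance to RL e13 replicate 1 on the mean of both classes and 0.67 in GCP-like cells, but 0.958 in progenitor-like cells, where 1 of the e14 libraries lay further off than RL e13 replicate 1. These distances use all cells, with only 52 GCP-like cells in RL e13 replicate 1, so sampling noise widens the distances to it. A wrong title with a right age tag of e14 stays open. Tlx3 in GCP-like cells, chosen after its values were seen, goes the other way in part, at 0.967 CPM in RL e13 replicate 1, 21.5 in RL e13 replicate 2 and 178 and 274 at e14, so a true age difference stays open.

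In every class compared, 7 genes stood 4-fold or more apart in 1 library, namely Cwc22, Gsta4, Tpm3-rs7, Lsamp, Nr2f2 and Rpl29 in the e16 library and Rpl26 in RL e13 replicate 1. Near-identical copies may explain part of them: 2 of the 7 shared 50% or more of their 3′ end with another gene, 14.8 times the rate of 103 of 5328 other genes (Fisher's exact test, two-sided p = 0.0076). For Gsta4, Lsamp and Nr2f2 this is argued against, as they shared at most 0.135% of it. No biological explanation was tested for these 3, and a difference of mouse strain, read mapping or age stays open.

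The 8 profiles of a comparison were split into 4 and 4 in all 35 ways. Of these, 1 split gave as many calls for GCP-like against progenitor-like cells, the real one with 2922, and the highest of the others gave 6. For cluster 5 against GCP-like cells it was again 1, the real one with 4273, and the highest of the others gave 3. The classes were clustered from the same values, which fixes this outcome beforehand, so the splits do not test chance for either comparison.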

How the results depend on the processing

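No gene called in a comparison changed sign in any alternative with a test. The removal of cells with the most UMIs, clustering resolution 2, the removal of roof plate-like clusters from the tests and every alternative of the cluster 5 comparison were chosen after seeing the data. For GCP-like against progenitor-like cells, 839 of the values of named genes kept direction and side of the threshold, 18 lost their call, 2 gained one and 2 reversed. For cluster 5, 25 lost their call and 6 reversed. In all of these the cause was not tested.

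Without the library block, 714 genes were higher in GCP-like than in progenitor-like cells. Leaving out 1 library gave 703 to 1270 higher and 1140 to 1893 lower genes in GCP-like against progenitor-like cells, highest without RL e13 replicate 1. It gave 1479 to 2620 and 1334 to 2495 in cluster 5, 0 to 214 and 0 to 304 for e14 against e13, and 365 to 384 and 293 to 321 for the e16 library. Grouping by age tag gave 48 and 20, with RL e13 replicate 1 alone on its side. With all cells pooled, 845 and 1023 genes stood apart in the e16 library, where class shares enter the value. With roof plate-like clusters left out, GCP-like shares were 73.4% in RL e14 replicate 1 and 57.2% in RL e13 replicate 2, and progenitor-like shares 13.9% and 31.2%.

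All reversed gene values belong to genes that were not called. In GCP-like against progenitor-like cells Mki67 reached -0.038 without the cells with the most UMIs, and -0.061 to 0.25 with 1 library left out, lowest without RL e14 replicate 2. In cluster 5 Kdm6a reached -0.0042 with TMM, -0.056 with 50 cells per profile and -0.017 with voom. With 1 library left out it went from -0.056 to 0.14 and Barhl1 from -0.25 to 0.074. For e14 against e13, Cbfa2t3 reached -0.0065 with a pseudocount of 20, and with 1 library left out Eomes went from -0.17 to 0.040, Barhl1 from -0.037 to 0.36 and Cbfa2t3 from -0.18 to 0.23. With all cells pooled Eomes stood at 1.90, Atoh1 at 0.37, Sox2 at -0.89 and Cbfa2t2 at 0.45, and the glia list turned (adjusted p = 0.263), where class shares enter the values.

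With the replicate number as a block limma called 0 genes higher and 0 lower between e14 and e13 (1430 at an unadjusted p under 0.05), and the deviations of same-numbered libraries correlated at 0.067. This value rests on too few libraries to show whether same-numbered libraries form pairs. At these cell numbers, a class under 20 cells in a library, such as cluster 5 with 5 cells in RL e13 replicate 1, gives no profile.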

Other observations

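Cluster 6, the other unnamed postmitotic cluster and mostly of the e16 library, was in no comparison. It carried Tlx3, a homeobox gene of glutamatergic neurons, at 375 CPM, where cluster 5 of the same library had 108. Eomes stood at 266 CPM against 115 in cluster 5 and Otx2 at 322 against 131. Barhl1, a gene of the granule lineage, stood at 135 against 464 CPM. The phospholipase gene Plcb1 (191 against 57.9), the glutamate transporter gene Slc17a6 (296 against 125) and the homeobox gene Lhx1 (132 against 31.7) were more abundant in cluster 6. Reln stood at 340 against 420.3 CPM and the potassium channel gene Kcnd2 at 66.8 against 77.4. Mki67 was at 6.28 CPM in cluster 6. These are values of 1 library with no replicate, and the genes were chosen after their values were seen.

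Tlx3 also varied between the libraries of 1 class. In GCP-like cells it stood at 0.967 CPM in RL e13 replicate 1, 21.5 in RL e13 replicate 2, and 178 and 274 in RL e14 replicates 1 and 2. In cluster 5 it stood at 23.1 CPM in RL e13 replicate 2, 145 and 165 in RL e14 replicates 1 and 2, and 108 in the e16 library. The corepressor partner gene Rcor2 stood at 75.9 to 187 CPM in cluster 5, against 24.5 to 41.6 in progenitor-like cells. Roof plate and choroid plexus genes marked clusters 15 and 16, with 190 and 30 cells, which were counted among the progenitor-like cells.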
